A study of Homo sapiens with 108 samples.

How the data were processed

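RNA from 18 ovarian cancer cell lines, each cultured with BLU-222 or DMSO for 24 h, was measured in 3 libraries per line and treatment. Per the labels' protocols the libraries were prepared from polyadenylated RNA with a NEBNext Ultra II kit. Per the submitters' processing notes the tools were Trim Galore, STAR 2.7.11b and Salmon 1.2 with the hg38 genome build. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes, and genes that share reads with near-identical copies, are uncertain. The authors deposited 1 table of estimated counts per gene symbol (expected counts, not normalized), with 29744 genes and 1 column per library. Every value in it was a whole number, so rounding changed nothing. Each column was matched to its sample by the sample's description, and 0 columns were without a sample.

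The total count per library ranged from 9936428 to 24007151. No pair of replicates was closer than sampling noise allows, since the lowest chi-square per degree of freedom between replicates was 2.35. A library was set apart when its mean correlation with its own line lay over 1.5 interquartile ranges below the first quartile, a multiple chosen after seeing the data.

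Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The main test was edgeR's quasi-likelihood test with TMM factors and Benjamini-Hochberg adjustment at 0.05. Genes with low counts were removed with a minimum count of 10 and a minimum total of 15, and for expression in DMSO against dose the minimum count had to be met in at least 5 lines. Log2 CPM values used a prior count of 2. Levels in CPM are means over 3 replicates.

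Across lines, the 3 libraries of each group were summed, and 36 sums were fitted with line as a block and treatment. Within a line, its 6 libraries were fitted by themselves. Differences between lines were tested with the 17 interaction terms of a fit of all libraries. Expression in DMSO, and the change with BLU-222, were fitted against log2 dose over the 18 lines. Cell cycle regulators in DMSO and the median changes of the lists were set against log2 dose with Pearson's and Spearman's coefficients and 100000 permutations, and again without the 2 lines farthest from the median dose of 320 nM (COV318 and Kuramochi). Fits with a replicate block, and the fits of other splits between lines, held the trended dispersion of the fit they are set beside.

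The 26 gene lists were written before the data were examined: cell cycle regulators, G1/S and E2F target genes, G2/M and mitotic genes, replication-dependent histone genes, p53 target genes, senescence secretory genes, NF-kB and TNF response genes, interferon-stimulated genes, antigen presentation genes, cholesterol synthesis genes, unfolded protein and integrated stress response genes, hypoxia response genes, MYC and ribosome biogenesis genes, ERK pathway output genes, immediate early and AP-1 genes, apoptosis regulator genes, the mesenchymal and epithelial arms of the epithelial-mesenchymal genes, lysosome and autophagy genes, DNA damage response and repair genes, ovarian tumor lineage genes, fibroblast, leukocyte and endothelial marker genes, mitochondrially encoded genes and heat shock genes. Of 892 members 877 were found, 75 of them by an older symbol. The mitochondrially encoded list had 0 of 13 members matched and gave no result, which left 25 lists. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

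Genes were named by a rule fixed in advance. Across lines it took the 10 largest rises and the 10 largest falls among genes that passed, with a mean log2 CPM of at least 2 and the same sign in at least 15 of 18 lines, up to 4 members with the smallest adjusted p of each list described, and any cell cycle regulator. Within a line it took the largest rise and the largest fall among genes that passed with a mean log2 CPM of at least 3 and all 3 BLU-222 libraries on the same side of all 3 DMSO libraries. Against dose it took the 6 steepest slopes each way among genes that passed, and none did. Between lines it ranked genes by the number of lines called in the rarer direction and took 6 with a mean log2 CPM of at least 3. All 6 came from 13 genes tied at 4 lines, by the smallest interaction p. The values of 1 gene that the rule named are not reported here.

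The share of other lines' transcripts, a measure chosen after seeing the data, was computed over genes whose mean CPM in a line was under 5% of their mean over the other 17 lines and whose mean there was over 5 CPM (231 to 957 genes per line). It is their summed CPM in a library as a percent of the same sum averaged over the other lines. The limit keeps the average share of a line under 5%. The measure does not tell transcripts of other lines from weak expression by the line itself.

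Alternatives fixed in advance were RLE factors, no filter on low counts, DESeq2, limma on the line differences, a replicate block, 1 fit of all libraries for the within-line results, dose in nM, leaving out lines, replicates or single libraries, the mean of a list and an estimated correlation. Chosen after seeing the data were the removal of the 6 ribosomal RNA genes, the ribosomal RNA share as a covariate, a GC trend as an offset, the removal of libraries that stood apart and the removal of genes under 20% of their level in the other lines. Gene positions are gene bodies of GENCODE v29 on GRCh38.

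The steps were tested on simulated counts with 200 changed genes each. Across lines a changed gene had the same fold change in every line, at a dispersion of 0.03. Within CaOV-3 the dispersion was 0.01. Recovery of effects that differ in size between lines, or in lines with a larger spread between replicates, was not tested for these fits. Across lines, 97% of 1.5-fold and 99% of 2-fold changes were recovered, with 12 false calls among 16245 genes. Within CaOV-3 73% and 91% were recovered (7 false calls, 14972 genes), and between lines with 3 lines changed 48% and 70% (6 false calls, 19007 genes). Against dose, slopes of 0.5 and 1 in DMSO were recovered for 30% and 98% of genes (4 false calls, 18314 genes), and slopes of 0.25 and 0.5 of the change for 75% and 97% (5 false calls, 16268 genes). A list of 40 genes shifted by 1.25-fold had a camera p of 9.5e-54 and an unshifted list 0.517.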

Results

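Transcripts were counted in libraries of polyadenylated RNA from 18 established ovarian cancer cell lines. Each line was cultured for 24 h with BLU-222, an inhibitor of the cyclin-dependent kinase CDK2, or with the solvent DMSO as the control. Each of the 36 groups held 3 biological replicates. The labels do not say whether the replicates came from separate cultures, so single-gene p-values within a line measure the spread between these libraries. Camera's list p-values within a line compare a list's genes with the other genes at a preset correlation. They do not measure the spread between libraries, and are given beside those with an estimated correlation. Each line was treated at 1 dose, its own IC50 according to the design text, so that dose and sensitivity are the same number here. The dose was 50 nM in COV318 and Kuramochi, 100 nM in NIH:OVCAR-3, 120 nM in CaOV-3, FU-OV-1 and OVSAHO, 200 nM in A2780, 260 nM in OAW42, 290 nM in OVMANA and 350 nM in TOV-112D. It was 380 nM in OVISE, 420 nM in OV-90, 650 nM in COV434, 770 nM in SK-OV-3, 850 nM in RMG-I, 1200 nM in TOV21-G, 1500 nM in RMUG-S and 1600 nM in COV644. As background, Kuramochi, OVSAHO and NIH:OVCAR-3 are used as models of high-grade serous carcinoma, OVISE, OVMANA, RMG-I and TOV21-G of clear cell carcinoma, and RMUG-S of mucinous carcinoma.

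The total count per library ranged from 9936428 in COV644 BLU-222 2 to 24007151 in RMG-I DMSO 2. Every library of the 36 groups correlated best with a library of their own line. Of the 29744 genes listed, 4264 had no count in any library. Ribosomal RNA transcripts took between 1.74% and 19.5% of the counts, with a mean of 4.21% in DMSO and 5.05% in BLU-222. This share was higher with BLU-222 in 12 of 18 lines, by 0.84 percentage points on average (SD 1.72, n = 18 lines, two-sided permutation test by sign flips p = 0.0539). In 3 libraries the correlation with the own line was low against the rest, namely OVISE DMSO 1, NIH:OVCAR-3 BLU-222 2 and NIH:OVCAR-3 BLU-222 3. Transcripts low in a line, at under 5% of their mean level in the other lines, were present in each library at a low share of that level. The 5% limit itself holds the average share of a line under 5%, and weak expression by the line itself counts toward the share. The median of this share was 3.55%, the lowest value was 0.717% in OVISE DMSO 1 and the next lowest was 1.37% in TOV-112D DMSO 3. It was higher with BLU-222 in 10 of 18 lines, by 0.272 percentage points on average (SD 0.692, n = 18 lines, two-sided permutation test by sign flips p = 0.0997).

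The first comparison asked which transcripts changed with CDK2 inhibition across the ovarian cancer lines as a set. Genes of mitosis fell in nearly every line. KIF20A, a kinesin of cytokinesis, fell by 1.30 on the log2 scale (SE 0.161, n = 18 lines, edgeR adjusted p = 6.15e-05) and was lower in 18 of 18 lines. PLK1, the polo-like kinase that drives mitotic entry, fell by 1.04 (SE 0.121, adjusted p = 2.98e-05) in 18 of 18 lines. The proliferation marker MKI67 fell by 0.93 (SE 0.157, adjusted p = 0.00097) in 17 of 18. Among genes with a mean log2 CPM of at least 2 and the same sign in at least 15 of 18 lines, the largest rise was that of PTGS1, the cyclooxygenase 1 gene, at 0.44 (SE 0.0778, adjusted p = 0.000752), higher in 17 of 18 lines.

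In total 2064 of 16264 tested genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05, of which 1172 rose and 892 fell, and 9 changed by at least 1 on the log2 scale. The balance depended on the setting, since falls outnumbered rises with no filter on low counts (777 rises, 783 falls), by limma on line differences (668 and 752) and without SK-OV-3 (852 and 859). Under the same limits on level and sign, the largest falls after KIF20A were those of the mitotic regulator CDCA3 at −1.15, the DNA helicase PIF1 at −1.14 and PLK1. They were followed by the centromeric histone CENPA at −0.97, BIRC5 (survivin) at −0.93, MKI67, the kinetochore gene NDC80 at −0.93, IQGAP3 at −0.89 (SE 0.186) and the centromeric kinesin CENPE at −0.88. PIF1, CENPA and BIRC5 were lower in 18 of 18 lines, and CDCA3, NDC80, IQGAP3 and CENPE in 17. Besides PTGS1, the largest rises under these limits were those of the carboxypeptidase CPA4 at 0.44 (SE 0.0865), the urokinase PLAU at 0.41 (SE 0.121, adjusted p = 0.0338), and the stress kinase p38-beta MAPK11 at 0.39 (SE 0.0529). They were followed by RINL at 0.38, the mucin glycosyltransferase GCNT3 at 0.38, MYO15B at 0.37, C15orf52 at 0.36, KIFC2 at 0.36 and ANKRD1 at 0.36. PLAU no longer passed by limma, with no filter on low counts, without replicate 2 or without any 1 of 8 lines, and MYO15B no longer passed by limma. Of these 10, MAPK11 was higher in 18 of 18 lines and the other 9 in 15 to 17. In the genome (GRCh38, GENCODE v29 gene bodies) KIF20A lies on chromosome 5 from 138178719 to 138187715, PLK1 on chromosome 16 from 23677656 to 23690367, MKI67 on chromosome 10 from 128096659 to 128126385 and PTGS1 on chromosome 9 from 122370530 to 122395703.

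Among the gene lists, the G2/M and mitotic genes fell most uniformly. Of 72 members, 71 fell over all genes tested and 72 adjusted over the list alone, with a median log2 change of −0.70 (camera adjusted p = 2.33e-82, and adjusted p = 0.0698 with an estimated correlation). CDC20, the activator of the anaphase-promoting complex, fell by 0.81 (SE 0.0829) in 17 of 18 lines, and the kinase gene AURKA by 0.81 (SE 0.0836) in 18 of 18. CCNB2 fell by 0.68 and BUB1 by 0.72, each in 17 of 18. Of the 70 G1/S and E2F target genes, which serve DNA replication, 15 fell over all genes and 29 adjusted over the list alone, with none rising (median −0.22, adjusted p = 2.29e-17, and adjusted p = 0.339 with an estimated correlation). The maintenance methyltransferase DNMT1 fell by 0.26 (SE 0.0623), the primase PRIM1 by 0.56 (SE 0.135), and the replicative helicase subunits MCM7 by 0.32 and MCM2 by 0.24.

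Of 34 replication-dependent histone genes measured, 11 fell over all genes and 17 adjusted over the list alone (median −0.39, adjusted p = 1.61e-11, and adjusted p = 0.177 with an estimated correlation). HIST1H3G fell by 1.23 (SE 0.212), HIST1H2BO by 1.13 (SE 0.219), HIST1H4B by 1.11 (SE 0.202) and HIST1H1E by 0.75 (SE 0.145). Most histone messages lack a poly(A) tail and their copies are close to identical, so levels of single histone genes in these libraries are uncertain. Of 41 DNA damage response and repair genes, 8 fell over all genes and 15 adjusted over the list alone (median −0.12, adjusted p = 1.51e-08, and adjusted p = 0.314 with an estimated correlation). They included the damage mediator MDC1 at −0.40 (SE 0.051), the histone variant H2AFX at −0.69 (SE 0.111), the checkpoint kinase WEE1 at −0.43 (SE 0.0898) and FANCE at −0.24.

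Of 32 cell cycle regulators, 2 rose and 8 fell over all genes, and 3 rose and 10 fell adjusted over the list alone (median −0.05, adjusted p = 0.000254, and adjusted p = 0.314 with an estimated correlation). CDKN1B, which encodes the CDK2 inhibitor p27, fell by 0.32 (SE 0.0311, adjusted p = 2.59e-06) in 18 of 18 lines. CCNA2, the cyclin A partner of CDK2, fell by 0.84 (SE 0.143) and CDK1 by 0.63 (SE 0.142). CCNB1 fell by 0.71, CDKN2C by 0.53, E2F2 by 0.39, RBL1 by 0.36 and CDKN2D by 0.34. CCND1, the cyclin D1 gene, rose by 0.23 (SE 0.0632) and CDK6 by 0.13 (SE 0.0424, adjusted p = 0.0441), each higher in 15 of 18 lines (14 and 13 with each line fitted by itself). CCNE1, the cyclin E1 partner of CDK2, had a log2 change of 0.24 (SE 0.11, adjusted p = 0.172) and was higher in 14 of 18 lines. CDK2 itself had a change of −0.18 (SE 0.0779, adjusted p = 0.145) and RB1 of −0.06 (SE 0.0433, adjusted p = 0.412). CDKN1A, the p21 gene, had a change of −0.01 (SE 0.0673, adjusted p = 0.932), whose sign turned under 5 alternative settings.

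Smaller falls were seen in 3 further lists. Of 20 heat shock genes 7 fell over all genes, and 11 fell and 1 rose adjusted over the list alone (median −0.08, adjusted p = 4e-05, and adjusted p = 0.277 with an estimated correlation). HSPA1B fell by 0.21 (SE 0.0405), HSPH1 by 0.13, DNAJB1 by 0.13 and STIP1 by 0.12. Of 28 immediate early and AP-1 genes 2 fell, adjusted over all genes and adjusted over the list alone (median −0.05, adjusted p = 0.0206, and adjusted p = 0.314 with an estimated correlation), namely FOS at −0.61 (SE 0.153) and EGR1 at −0.49 (SE 0.115). Of 44 MYC and ribosome biogenesis genes 1 fell over all genes, WDR74 at −0.10 (SE 0.0278), and 0 adjusted over the list alone (median −0.03, adjusted p = 0.0121, and adjusted p = 0.578 with an estimated correlation).

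The lists that rose numbered 8 of 25. Of 34 senescence secretory genes 7 rose over all genes and 10 adjusted over the list alone (median 0.15, adjusted p = 0.000325, and adjusted p = 0.314 with an estimated correlation), among them IGFBP5 at 0.41 (SE 0.0889), ANGPTL4 at 0.43 (SE 0.0974) and TIMP1 at 0.16. Of 35 genes of the mesenchymal arm of the epithelial-mesenchymal list 8 rose over all genes and 10 adjusted over the list alone (median 0.11, adjusted p = 0.00223, and adjusted p = 0.177 with an estimated correlation), with the matrix genes SPARC at 0.32 (SE 0.0729), COL5A1 at 0.30 (SE 0.0772) and COL6A2 at 0.19. Of 35 lysosome and autophagy genes 7 rose over all genes and 10 adjusted over the list alone (median 0.07, adjusted p = 0.00157, and adjusted p = 0.477 with an estimated correlation), with WIPI1 at 0.26 (SE 0.0489), the hydrolases GAA at 0.16 and HEXA at 0.13, and the cholesterol carrier NPC2 at 0.15. Of 45 interferon-stimulated genes 6 rose over all genes and 8 adjusted over the list alone (median 0.12, adjusted p = 0.000212, and adjusted p = 0.336 with an estimated correlation), with SAMD9L at 0.33 (SE 0.0954), OAS1 at 0.26, IFI6 at 0.16 and STAT2 at 0.15.

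Of 25 cholesterol synthesis genes 5 rose over all genes and 6 adjusted over the list alone (median 0.07, adjusted p = 0.0088, and adjusted p = 0.477 with an estimated correlation), with TM7SF2 at 0.25 (SE 0.0651), MSMO1 at 0.20 (SE 0.0391), MVD at 0.16 and SC5D at 0.15. Of 31 hypoxia response genes 6 rose over all genes and 7 adjusted over the list alone (median 0.04, adjusted p = 0.0221, and adjusted p = 0.314 with an estimated correlation), with PFKFB4 at 0.24 (SE 0.0589), AK4 at 0.24 (SE 0.0429) and P4HA2 at 0.20. Of 26 antigen presentation genes 2 rose over all genes, HLA-DPA1 at 0.65 (SE 0.198, adjusted p = 0.0319) and HLA-DMA at 0.16 (SE 0.0525, adjusted p = 0.0497), and 0 adjusted over the list alone (median 0.05, adjusted p = 0.048, and adjusted p = 0.477 with an estimated correlation). Of 34 epithelial arm genes 0 passed edgeR's test over all genes or adjusted over the list alone while the list was shifted upward (median 0.07, adjusted p = 0.0232, and adjusted p = 0.652 with an estimated correlation). KRT19, at 0.26, was the nearest to passing (adjusted p = 0.0755). In TOV-112D, where the epithelial list rose most, the share of other lines' transcripts stood at 1.44% in DMSO and 3.92% in BLU-222. OVISE DMSO 1, which stood apart, had median log2 differences from DMSO 2 and 3 of −0.744 (mesenchymal arm), −0.498 (antigen presentation) and −0.41 (senescence secretory). They were −0.211 (epithelial arm), −0.185 (lysosome), −0.0428 (interferon-stimulated), 0.109 (cholesterol synthesis) and 0.0498 (hypoxia). Values below 0 add to the rise of a list in this line.

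The remaining 9 lists did not pass as lists by camera. By fry the p53 target genes (adjusted p = 0.0246) and the NF-kB and TNF response genes (0.0411) passed. The MYC and ribosome biogenesis (0.318), epithelial (0.206) and immediate early (0.0723) lists, which camera called, did not pass by fry. The other lists that camera called also passed by fry. Of 57 p53 target genes 8 rose and 1 fell over all genes, and 10 rose and 2 fell adjusted over the list alone (list adjusted p = 0.174), including the p53-inducible genes TP53INP1 at 0.26 (SE 0.0743), SYTL1 at 0.25, TP53I3 at 0.20 and the death receptor FAS at 0.18. Of 32 NF-kB and TNF response genes 2 rose, LTB at 0.40 (SE 0.11) and SDC4 at 0.17 (SE 0.0453), also adjusted over the list alone (list adjusted p = 0.0825). Of 33 unfolded protein and integrated stress response genes 3 rose and 1 fell over all genes, and 5 rose and 4 fell adjusted over the list alone (list adjusted p = 0.906). In that list the endoplasmic reticulum genes CRELD2 and SDF2L1 rose by 0.20 (SE 0.032) and 0.18 (SE 0.0368). Of 19 ERK pathway output genes 2 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.115), namely CCND1, ETV5 at 0.20 (SE 0.0637) and EGR1. Of 26 apoptosis regulators 2 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.776), namely CASP8 at 0.19 (SE 0.0529), BAD at 0.11, PMAIP1 at −0.22 (SE 0.0693) and BCL2L11 at −0.18. Of 25 ovarian tumor lineage genes 2 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.293), namely MSLN (mesothelin) at 0.33 (SE 0.0655), FOLR1 at 0.22 and ARID1A at −0.15. Of the marker genes of other cell types, 0 of 10 fibroblast genes, 0 of 7 leukocyte genes and 0 of 7 endothelial genes passed edgeR's test over all genes or adjusted over the list alone (list adjusted p = 0.776, 0.584 and 0.351). The smallest adjusted p over all genes was 0.166 for the fibroblast gene LUM, 0.177 for CSF1R and 0.255 for VWF. In the apoptosis list the median (0.02) and mean (0.003423) lay above 0 and the test's direction below it, and in the stress response list the mean (0.01) and the test also differed in sign.

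Genes that rose had a higher median GC content (56.1%) than the tested genes (50.5%) and genes that fell a lower one (48.4%), and the antigen presentation and epithelial lists lost their calls with a GC trend as an offset (adjusted p = 0.112 and 0.102). The count of called genes was 1361 without replicate 1 of every group, and without replicate 2 the immediate early (adjusted p = 0.145), hypoxia (0.144), antigen presentation (0.182) and epithelial (0.0572) lists did not pass.

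**Figure D1:**
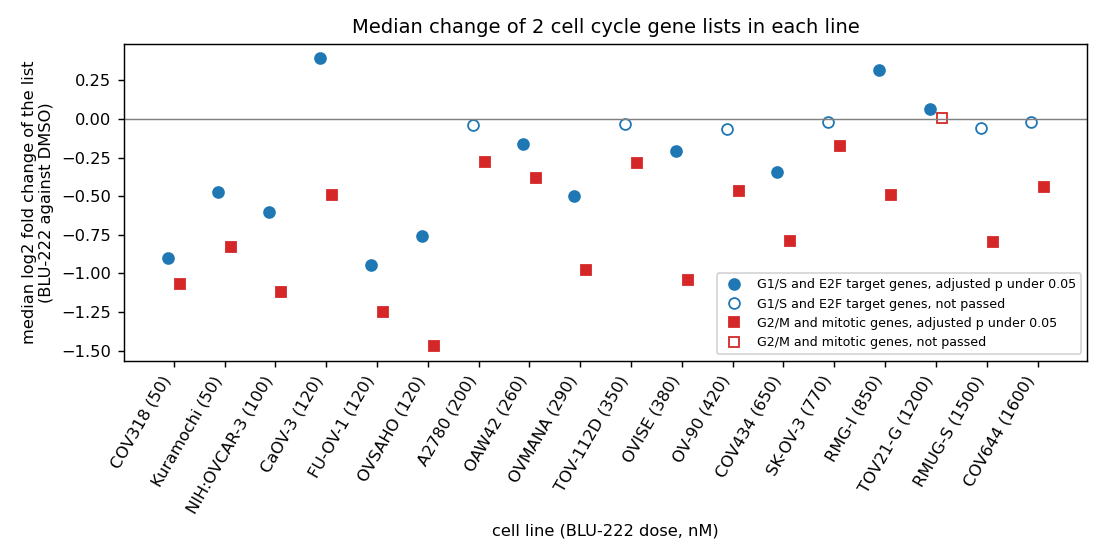
Median log2 fold change, BLU-222 against DMSO, of the members of 2 cell cycle gene lists in each of the 18 cell lines, with the lines in order of dose in nM and filled points where the list passed. The G2/M and mitotic medians lie between −1.47 in OVSAHO and 0.01 in TOV21-G, and those of the G1/S and E2F target genes between −0.95 in FU-OV-1 and 0.39 in CaOV-3.

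The second comparison asked what changed in each line by itself. Mitotic genes fell in most lines but the amount of change ranged widely, from 4425 called genes in FU-OV-1 to 0 in OAW42 and OV-90. The counts and the order of the lines depended on the fit. A fit of all libraries with a shared spread called 2506 genes in FU-OV-1, 1407 in OVISE, 1388 in NIH:OVCAR-3, 1243 in COV644, 585 in CaOV-3 and 546 in Kuramochi. It called 74 in OV-90, 29 in OAW42, 23 in A2780 and 13 in TOV21-G, and edgeR with the ribosomal RNA share as a covariate called 755 in OV-90 and 0 in OAW42. BIRC5, CDC20, CDCA3, KIF20A, MKI67 and PLK1 were called lower in 15 of 18 lines and higher in 0. Of 11139 genes tested in all 18 lines, 97 fell in at least 10 lines, where calls independent between lines would give 1.49e-06, and 0 rose in at least 10. Rises recurred in fewer lines, with 78 genes in at least 6 lines against 0.331 by independence, and 22 in at least 7 against 0.0142. Some genes may pass more easily than others in every line, so these expectations alone do not show a shared effect. The largest recurrence of a rise was 8 lines, reached by CHPF, which helps to build chondroitin chains, and CUL7, a cullin of ubiquitin ligases, the only 2 genes to reach it, both named after their values were seen.

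Called genes by edgeR numbered 4425 of 14385 tested in FU-OV-1 (2188 higher, 2237 lower), 3677 in RMG-I (1889 higher, 1788 lower), 3512 in CaOV-3 (1890 higher, 1622 lower) and 2506 in Kuramochi (1165 higher, 1341 lower). With 1 of the 6 libraries left out in turn these counts ran from 3337 to 4741, 2658 to 4095, 2636 to 3510 and 1765 to 2209. The count was 1902 in COV434 (1139 to 1760 with 1 library left out), 1879 in TOV-112D (1174 to 1549), 1392 in OVSAHO (705 to 2129), 948 in COV318 (424 to 2069) and 740 in A2780 (272 to 1050). It was 449 in OVMANA (252 to 432), 442 in SK-OV-3 (111 to 736), 323 in RMUG-S (122 to 470), 271 in COV644 (15 to 680), 106 in NIH:OVCAR-3 (21 to 217) and 14 in TOV21-G (1 to 152). In OVISE 21 genes rose and 87 fell (0 to 879 in all with 1 library left out). In OAW42 edgeR called 0 of 14101 genes and DESeq2 10, with 852 at an unadjusted p under 0.05. In OV-90 edgeR called 0 of 14335 genes and DESeq2 59, with 716 at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 9 genes in OAW42 and 0 in OV-90, and it moved the count of a line by over 1.5 times for 49 libraries, in 13 lines. With the ribosomal RNA share as a covariate the count was 2562 in OVISE, 2122 in OVSAHO, 952 in Kuramochi, 755 in OV-90, 210 in COV318, 71 in RMUG-S, 41 in SK-OV-3, 11 in COV644 and 0 in NIH:OVCAR-3. In the other 9 lines it moved by less than 1.5 times. The G2/M list fell in OAW42 (median −0.38, camera adjusted p = 4.03e-22, and adjusted p = 0.5 with an estimated correlation) and in OV-90 (median −0.47, adjusted p = 3.22e-61, and adjusted p = 0.0548 with an estimated correlation) although 0 of its members passed in either line by edgeR. In OAW42 the ribosomal RNA share was 4.41% in DMSO and 7.34% in BLU-222, higher in every BLU-222 library than in any DMSO library.

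In each line the gene with the largest fall and the gene with the largest rise were often not the same as in other lines. FAM111B, a replication-linked protease, fell from 27.8 ± 4.58 to 4.13 ± 0.512 CPM (SD, n = 3) in COV318 (log2 change −2.76, edgeR adjusted p = 8.26e-07). The reductase gene DHRS2 fell from 27.9 ± 1.94 to 4.33 ± 0.862 CPM in FU-OV-1 (−2.69, edgeR adjusted p = 1.57e-14), and IQGAP3 from 260 ± 20.7 to 41.7 ± 6.97 CPM in OVSAHO (−2.64). Among mitotic genes, KIF20A fell from 70.8 ± 4.15 to 30.3 ± 3.11 CPM in COV434 and from 43.4 ± 2.56 to 10.5 ± 0.0957 CPM in RMG-I. CDCA3 fell from 40.9 ± 5.17 to 9.78 ± 1.83 CPM in OVISE and from 39.3 ± 4.29 to 9.6 ± 0.956 CPM in OVMANA. PIF1 fell by 1.43 on the log2 scale in Kuramochi and by 2.01 in NIH:OVCAR-3, and PLK1 from 120 ± 11.8 to 51.1 ± 9.28 CPM in COV644. The histone gene HIST1H2AC fell by 2.24 in CaOV-3, TNFAIP8L1 by 1.86 in RMUG-S and the metallothionein gene MT2A by 1.04 in SK-OV-3. Smaller were the largest falls of the protocadherin gene PCDH10 by 0.80 in TOV-112D, the spindle orientation gene GPSM2 by 0.72 in A2780 and the nuclear receptor gene NR4A1 by 0.56 in TOV21-G.

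The largest rise in RMG-I was that of CYP24A1, the vitamin D 24-hydroxylase, from 4.58 ± 1.56 to 17.4 ± 1.49 CPM (n = 3, log2 change 2.00, SE 0.163, edgeR adjusted p = 4.31e-09). MYO15B rose from 18.9 ± 2.53 to 59.3 ± 12 CPM in FU-OV-1, the interferon-stimulated gene XAF1 from 5.84 ± 1.06 to 16.9 ± 4.84 CPM in COV644, and the growth factor carrier FGFBP1 from 6.1 ± 0.652 to 15 ± 1.98 CPM in OVISE. Thrombomodulin (THBD) rose by 1.26 in CaOV-3, the procollagen protease ADAMTS14 by 1.16 in SK-OV-3, MAGED4B by 1.10 in COV434, MYH15 by 1.08 in RMUG-S, and the amino acid transporter SLC6A14 by 1.04 in OVMANA. SPDYE2B rose by 1.02 in COV318, PTGS1 by 0.91 in NIH:OVCAR-3, TMEM132B by 0.87 in Kuramochi and TCFL5 by 0.52 in TOV21-G. RMRP, an RNA without a poly(A) tail, rose by 1.24 in OVSAHO, and the reads of MAGED4B and SPDYE2B are shared with near-identical copies, so these 3 are uncertain. The calls of SPDYE2B, PTGS1, RMRP, FGFBP1, XAF1, ADAMTS14, TCFL5, NR4A1, UPK3B, PIF1 in NIH:OVCAR-3 and CDCA3 in OVISE were each lost with a library left out, the ribosomal RNA covariate or another tool or filter. IGFN1 rose from 5.06 ± 1.43 to 20.3 ± 2.72 CPM in TOV-112D and UPK3B from 6.43 ± 0.825 to 11.6 ± 2.85 CPM in A2780. Both stood far below the other lines, IGFN1 at 3.48% and UPK3B at 3.55% of the mean of the other 17.

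The rises in TOV-112D went with a difference in the share of transcripts of the other lines, a measure computed from genes low in the line. This share was 1.54%, 1.41% and 1.37% in its DMSO libraries, the lowest of the series after OVISE DMSO 1. In its BLU-222 libraries it was 3.69%, 4.38% and 3.68%, within the range of the other lines, with a series median of 3.55%. Of 306 genes that rose there by at least 1 on the log2 scale, 297 had a level under 20% of the mean of the other lines, and without such genes, a choice made after seeing the data, 1336 genes were called in place of 1879. In OVISE, DMSO 1 had 0.717% of such transcripts against 3.36% to 3.89% in the line's other libraries, and 879 genes were called without it, against 21 rises and 87 falls with it.

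Over all lines and lists, 153 of 443 list tests passed, and 3 of these with an estimated correlation. The G2/M and mitotic genes fell in 17 of 18 lines and in 0 rose. Their median was lowest in OVSAHO at −1.47 (adjusted p = 0.0959 with an estimated correlation), and the calls held with an estimated correlation in FU-OV-1 (adjusted p = 0.0165), Kuramochi (0.0353) and NIH:OVCAR-3 (0.0421). In NIH:OVCAR-3, BLU-222 2 and 3 stood apart, the ribosomal RNA share was 4.37% in DMSO and 7.41% in BLU-222, and with this share as a covariate edgeR called 0 genes in place of 106 (DESeq2 255 without the covariate). In TOV21-G, treated at 1200 nM, the G2/M list did not pass and its median was 0.01. The G1/S and E2F target genes fell in 9 lines and rose in 3. They rose in CaOV-3 (63 of 70 members, median 0.39, adjusted p = 1.02e-27, and adjusted p = 0.0548 with an estimated correlation), in RMG-I (55 of 70, median 0.31, adjusted p = 1.05e-20, and adjusted p = 0.0742 with an estimated correlation) and in TOV21-G (0 of 70 by edgeR, median 0.06, adjusted p = 0.00038, and adjusted p = 0.415 with an estimated correlation). In CaOV-3 and RMG-I the G2/M genes fell at the same time, with 63 and 55 of 72 members lower and medians of −0.49 and −0.49 (adjusted p = 0.0839 and 0.0742 with an estimated correlation).

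The DNA damage response and repair genes fell in 11 lines and rose in 3, with medians from −0.55 in COV318 to 0.26 in RMG-I, and the cell cycle regulators fell in 9 and rose in 1. Histone genes fell in 8 lines and rose in COV434, where 8 of 22 members rose (median 0.70, adjusted p = 4.43e-07, and adjusted p = 0.0742 with an estimated correlation). Senescence secretory genes, interferon-stimulated genes, mesenchymal arm genes and lysosome genes each rose in 8 lines. TOV-112D, where genes low against the other lines rose, was among these lines for each of these lists but the lysosome genes. The interferon-stimulated genes fell in Kuramochi, where 26 of 45 members were lower (median −0.25, adjusted p = 5.27e-11, and adjusted p = 0.146 with an estimated correlation), and the lysosome genes fell in COV644 (median −0.18, adjusted p = 0.000451, and adjusted p = 0.54 with an estimated correlation). In COV644 the ribosomal RNA share was 6.5% in DMSO and 10.4% in BLU-222, and with this share as a covariate edgeR called 11 genes in place of 271. In RMG-I the ERK pathway output genes rose most, with 16 of 19 members higher (median 0.76, adjusted p = 3.43e-11, and adjusted p = 0.113 with an estimated correlation), together with 29 of 44 MYC and ribosome biogenesis genes (median 0.23, adjusted p = 5.36e-08, and adjusted p = 0.146 with an estimated correlation).

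Further lists passed in fewer lines. Heat shock genes fell in 8 lines, MYC and ribosome biogenesis genes fell in 7 and rose in 1, immediate early genes fell in 4, and stress response genes fell in 3 and rose in 1. Cholesterol synthesis genes rose in 5 lines and fell in 1, NF-kB and TNF response genes rose in 5 and fell in 2, and antigen presentation genes rose in 4. Hypoxia genes rose in 3 lines, p53 target genes in 2, and ERK pathway output genes rose in 2 and fell in 2. The epithelial arm rose in 3 lines and fell in 1, and the ovarian lineage genes and the fibroblast and endothelial markers each rose in 1. Apoptosis regulators and leukocyte markers passed in 0 by camera. None of the calls of this kind named here, beyond the 3 given, held with an estimated correlation, where the lowest adjusted p of the others was 0.0548.

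In TOV-112D, 24 of 29 epithelial arm genes rose (median 1.70, adjusted p = 2.26e-20, and adjusted p = 0.096 with an estimated correlation), as did 9 of 20 lineage genes and 14 of 26 senescence secretory genes (adjusted p = 0.0839 and 0.221 with an estimated correlation). All 3 lists moved with the share of other lines' transcripts, which was lower in DMSO than in BLU-222. Without the genes at under 20% of the other lines' level their adjusted p was 0.981, 0.417 and 0.12. That filter leaves few epithelial arm genes to test, since 31 of the 34 listed stood under 5% of the other lines' level. In that setting 3 of the 10 lists called in TOV-112D passed, the G2/M (adjusted p = 3.8e-33), cholesterol synthesis (0.00718) and heat shock genes (0.00385). The interferon-stimulated genes had 0.0544, antigen presentation genes 0.165, the mesenchymal arm 0.404 and NF-kB and TNF response genes 0.451. In OVISE the fibroblast markers rose as a list with 0 of 7 members called by edgeR (median 0.62, adjusted p = 0.0496, and adjusted p = 0.673 with an estimated correlation), and these markers were lower in DMSO 1 than in DMSO 2 and 3, by a median of 2.93 on the log2 scale.

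The third comparison tested whether the effect of BLU-222 differed between lines. At most 4 lines were called in the rarer direction, for 13 genes, and the 6 of these with the smallest interaction p are given. RRM2, a subunit of ribonucleotide reductase, was called higher in 4 lines and lower in 8, with log2 changes from −2.13 in FU-OV-1 to 0.85 in CaOV-3 (edgeR interaction adjusted p = 7.13e-33). Another of the 6, the replication licensing factor CDC6, was called higher in 5 lines and lower in 4, from −1.11 in COV318 to 0.78 in RMG-I. TCF19, ASF1B, KIAA0101 and FAM111B were each called higher in 4 lines, and lower in 6, 5, 6 and 6, with the highest value in CaOV-3 for each.

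The line by treatment terms passed for 4987 of 19127 genes, and 1632 of the 2151 genes called in opposite directions in different lines were among them. Of the 127 genes named across lines, within a line or between lines, 88 differed between lines, including the 6 chosen for calls in opposite directions. CDKN1B had an adjusted p of 0.0813 in this test, MAPK11 of 0.188 and MSLN of 0.714, with CDKN1B lower in 18 of 18 lines. CCNE1 was called higher in 4 lines and lower in 3, from −0.82 in FU-OV-1 to 1.05 in RMG-I, and CDK2 higher in 2 and lower in 6, from −0.86 in FU-OV-1 to 0.34 in RMG-I, and both differed between lines. The count of 4987 genes was between 1773 and 2591 when replicate 1, 2 or 3 was left out of every group. It was 5903 of 19834 without the libraries that stood apart. These counts include the rises in TOV-112D that went with the share of other lines' transcripts, and the fit was not repeated without those genes.

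The series title concerns tumors with aberrant CCNE1, so the next comparison set the transcript levels of cell cycle regulators in DMSO against the dose of the line. Lines treated at a low dose tended to have more CCNE1 and more CDKN2A, the p16 gene, but 0 of 32 regulators passed after adjustment by permutation test, with 0 by either coefficient. CCNE1 was highest in FU-OV-1, at 230 ± 10.5 CPM (SD, n = 3), followed by OVISE at 111 ± 11.3, OVMANA at 87.6 ± 10.6 and NIH:OVCAR-3 at 72.9 ± 2.96, and lowest in TOV21-G at 13.2 ± 1.15. CDKN2A ranged from 644 ± 53.6 CPM in NIH:OVCAR-3 and 553 ± 31.2 in COV318 to 7.67 ± 1.16 in RMG-I and 6.16 ± 0.565 in SK-OV-3. RB1 was lowest in CaOV-3, at 1.09 ± 0.453 CPM, then in OVSAHO at 12.7 ± 0.717, and highest in RMG-I at 90.7 ± 4.31. CCNE1 lies on chromosome 19 from 29811898 to 29824308, CDKN2A on chromosome 9 from 21967753 to 21995301 and RB1 on chromosome 13 from 48303726 to 48599436.

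Over 18 lines the log2 CPM of CCNE1 in DMSO had Pearson's r = −0.588 with log2 dose (permutation p = 0.0103, adjusted over 32 genes 0.15) and Spearman's rho = −0.653 (permutation p = 0.00421, adjusted 0.0674). Without COV318 and Kuramochi, the lines farthest from the median dose, r was −0.663. CDKN2A had r = −0.625 (permutation p = 0.0055, adjusted 0.15), rho = −0.668 (permutation p = 0.00292, adjusted 0.0674) and r = −0.538 without the same lines. RB1 had r = 0.361 (permutation p = 0.14, adjusted 0.408), rho = 0.367 (permutation p = 0.134, adjusted 0.39) and r = 0.565 without them. At an unadjusted permutation p under 0.05 for r were also CDKN1A (r = 0.547), RBL2 (r = 0.571), CCNA1 (r = −0.507) and E2F3 (r = −0.472).

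**Figure D2:**
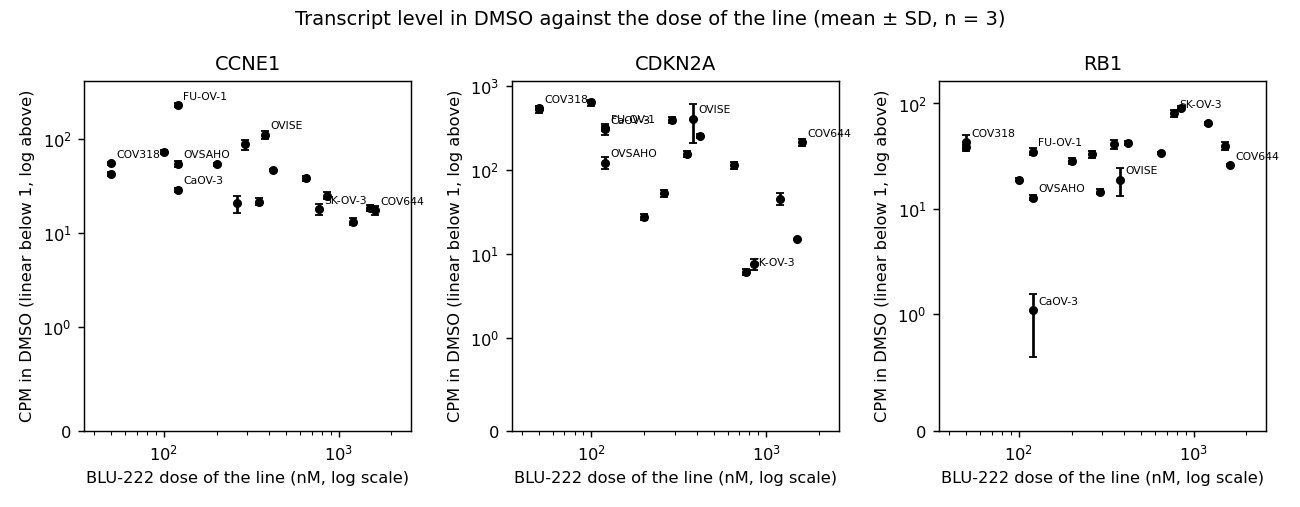
Mean CPM in DMSO of CCNE1, CDKN2A and RB1 in each of the 18 lines (y axis) against the BLU-222 dose of the line in nM (x axis, log scale), with the SD of 3 replicates as bars. CCNE1 reached 230 CPM in FU-OV-1 and RB1 was lowest at 1.09 CPM in CaOV-3, both treated at 120 nM.

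Across all genes, expression in DMSO against log2 dose gave 0 of 17446 genes by edgeR at an adjusted p under 0.05, with 2216 at an unadjusted p under 0.05 and 897 by DESeq2. As lists, the interferon-stimulated genes were lower in lines treated at a higher dose, with a median slope of −0.32 log2 units for each doubling of dose (adjusted p = 2.54e-10, and adjusted p = 0.825 with an estimated correlation). The p53 target genes were higher (median slope 0.19, adjusted p = 8.04e-05), as were the epithelial arm (0.30, adjusted p = 0.0198) and the DNA damage response genes (0.06, adjusted p = 0.0359), while the MYC and ribosome biogenesis genes were lower (−0.09, adjusted p = 0.00223). These 4 also had an adjusted p of 0.825 with an estimated correlation. The other 20 lists did not pass, and 0 members of any list passed by edgeR. In simulated data a slope of 0.5 log2 units was recovered for 30% of genes and a slope of 1 for 98%.

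The change with BLU-222 was set against the dose in the same way. The cell cycle lists fell most in lines treated at a low dose. The median change of the G1/S and E2F target genes rose with log2 dose (r = 0.605, permutation p = 0.00802, adjusted over 3 measures 0.0241; rho = 0.62, permutation p = 0.00705, adjusted 0.0211), with r = 0.498 without COV318 and Kuramochi. That of the G2/M and mitotic genes did as well (r = 0.54, permutation p = 0.0217, adjusted 0.0325; rho = 0.561, permutation p = 0.0168, adjusted 0.0252), with r = 0.517 without these lines. Without replicate 2 the rho of the G2/M genes was 0.498 (adjusted p = 0.0551) and no longer passed. The number of genes called within a line had r = −0.315 with log2 dose (permutation p = 0.203, adjusted 0.203; rho = −0.318, permutation p = 0.196, adjusted 0.196) and r = −0.311 without them. With the dose in nM, r was 0.486 for the G1/S and 0.44 for the G2/M genes, and both had an adjusted p of 0.102.

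By list test, the slope of the change on log2 dose was 0.15 for the G1/S genes (adjusted p = 1.94e-44), 0.13 for the G2/M genes (adjusted p = 1.72e-31), 0.09 for the DNA damage response genes (adjusted p = 2.14e-13) and 0.05 for the cell cycle regulators (adjusted p = 3.52e-07). It was −0.04 for the lysosome genes (adjusted p = 1.74e-08), and each of these 5 had an adjusted p of 0.22 with an estimated correlation. Slopes below 0 were also found for stress response genes (−0.04, adjusted p = 0.00353, and adjusted p = 0.422 with an estimated correlation) and antigen presentation genes (−0.03, adjusted p = 0.0334, and adjusted p = 0.621 with an estimated correlation). MYC and ribosome biogenesis genes had a slope of 0.01 (adjusted p = 0.00636, and adjusted p = 0.707 with an estimated correlation) and heat shock genes of 0.01 (adjusted p = 0.0231, and adjusted p = 0.621 with an estimated correlation). The other 16 lists did not pass. For single genes edgeR called 0 of 16264, with 1404 at an unadjusted p under 0.05 and 21 by DESeq2. With same-numbered replicates as blocks 678 of 14730 passed. That fit takes the replicate pairs of a line as independent units, although the dose differs only between lines. The replicate numbers also did not pair the samples (median correlation 0.002).

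**Figure D3:**
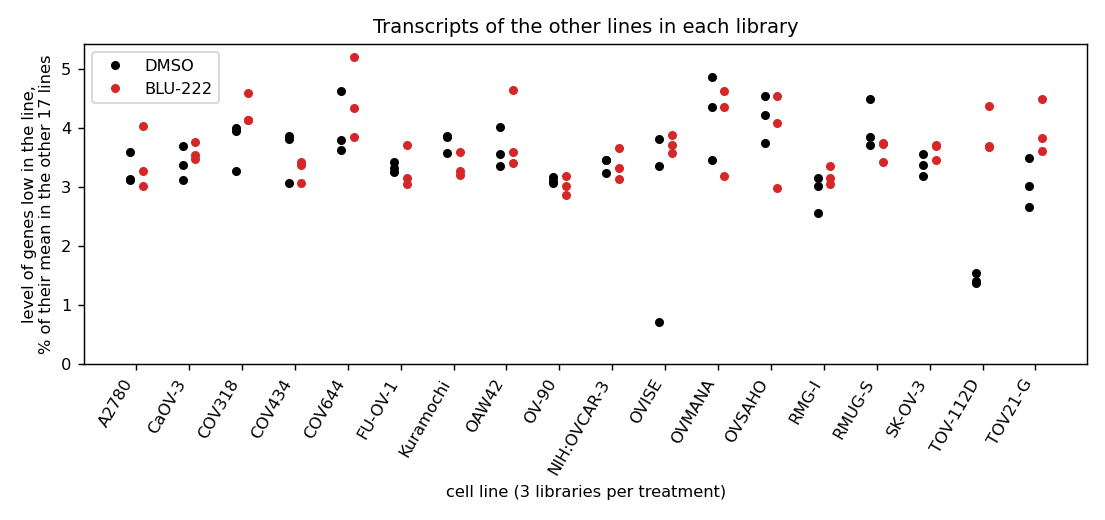
Share of other lines' transcripts in each library, as a percent of their mean level in the other 17 lines (y axis), by line (x axis) and treatment. The TOV-112D libraries lay at 1.37% to 1.54% in DMSO and 3.68% to 4.38% in BLU-222, and OVISE DMSO 1 at 0.717% lay below all other libraries.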

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

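The tests chosen only after the result was seen were those of a single other line as the source in TOV-112D, of a preparation apart for OVISE DMSO 1, and of RB1 and of dose for the G1/S genes, which took the place of earlier tests made over both lines at once. Of 127 genes named across lines, within a line or between lines, the last 6 chosen for calls in opposite directions, 88 had a BLU-222 effect that differed between lines by the interaction test of edgeR (adjusted p under 0.05), and the genes reported here are listed with the SD of their log2 change over the 18 lines. Genes named for their rises across lines had PTGS1 0.41, CPA4 0.42, PLAU 0.55, RINL 0.43, GCNT3 0.71, MYO15B 0.50, C15orf52 0.27, KIFC2 0.29 and ANKRD1 0.45. Genes named for their falls had KIF20A 0.68, CDCA3 0.72, PIF1 0.69, PLK1 0.52, CENPA 0.52, BIRC5 0.58, MKI67 0.67, NDC80 0.56, IQGAP3 0.78 and CENPE 0.46.

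Among cell cycle regulators the SD over lines was CCNB1 0.39, CCNA2 0.61, CDKN2C 0.51, RBL1 0.38, CDK1 0.60, CCND1 0.29, E2F2 0.54, CDK2 0.35, CCNE1 0.47, RB1 0.18 and CDKN1A 0.32. For replication and mitotic list members it was DNMT1 0.28, PRIM1 0.61, MCM7 0.35, MCM2 0.30, CDC20 0.37, CCNB2 0.34, AURKA 0.37 and BUB1 0.34. For p53, senescence, NF-kB, interferon, cholesterol, stress response and hypoxia list members it was TP53I3 0.21, SYTL1 0.34, TP53INP1 0.37, IGFBP5 0.46, SDC4 0.21, LTB 0.52, OAS1 0.49, STAT2 0.20, TM7SF2 0.30, XPOT 0.15, MANF 0.18 and P4HA2 0.18. For the other list members it was EGR1 0.49, ETV5 0.30, FOS 0.65, CASP8 0.28, BCL2L11 0.24, PMAIP1 0.31, COL6A2 0.21, WIPI1 0.21, GAA 0.20, MDC1 0.24, H2AFX 0.48, WEE1 0.40, FANCE 0.23, FOLR1 0.32 and HSPA1B 0.17. Genes called in opposite directions had TCF19 0.63, RRM2 0.90, ASF1B 0.59, CDC6 0.53, KIAA0101 0.64 and FAM111B 0.96. Genes named within a line had UPK3B 0.43, GPSM2 0.34, THBD 0.86, HIST1H2AC 0.63, XAF1 0.49, DHRS2 0.91, FGFBP1 0.60, CYP24A1 0.93, MYH15 0.80, TNFAIP8L1 0.48, ADAMTS14 0.65, MT2A 0.49, IGFN1 0.69, PCDH10 0.64, TCFL5 0.29 and NR4A1 0.43. Among the 39 genes whose effect did not pass this test were CDKN1B (adjusted p = 0.0813) and MAPK11 (adjusted p = 0.188), and a p that misses the threshold does not show equal effects.

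In TOV-112D genes near 0 in DMSO rose with BLU-222. Of 804 genes low in this line 779 (96.9%) were higher in its BLU-222 libraries. A general difference in the share of transcripts of the other lines predicted such a rise of nearly all of them. The share is computed from these same 804 genes, so it restates their rise and cannot by itself account for it. It was the DMSO libraries that lay apart, at 1.37% to 1.54%, the lowest of the series after OVISE DMSO 1. The BLU-222 libraries, at 3.68% to 4.38%, lay within the range of the other lines, with a series median of 3.55%. RNA of a single other line is argued against by the increases, which followed the mean of the other lines (rho over genes 0.91) more closely than any single line (0.673), a difference of 0.237. That test took the place of an earlier one, in which genes specific to TOV21-G gained most, at 5.09 times the gain of the median line, with gains above 0 for 16 of 16 lines. The increase of the epithelial genes low in this line was 0.954 times the one the share predicts (interquartile range 0.851 to 1.12, 31 genes). These 31 genes are among the 804 from which the share was computed, which draws the ratio toward 1. The ratio therefore cannot decide whether epithelial genes were induced, and how the share came to differ stays open.

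OVISE DMSO 1 lay apart from the other 5 OVISE libraries. Another line mixed in is argued against, since the highest median share of any of 17 lines was 0.177%, while the summed share was 2.29% for SK-OV-3, over 5 genes with a median of 0, and at most 0.365% for the others. Its difference from DMSO 2 and 3 followed transcript GC content (rho over genes −0.531), so a GC bias may contribute. Among genes with a mean log2 CPM of at least 5, its largest falls against DMSO 2 and 3 were of noncoding RNAs. These were RNA5-8S5, RN7SL1, RMRP, RN7SL2, BCYRN1 and RN7SK, with RN7SL1 at 89.9 CPM against 1800 and 1850. The share of other lines' transcripts in this library, 0.717%, lay below that of all other libraries of the series (SD 0.615). A preparation or sequencing of OVISE DMSO 1 apart from the rest therefore also stays open. Its G2/M genes lay 0.125 above DMSO 2 and 3 and 1.12 above BLU-222 on the log2 scale, and no biological explanation was tested.

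In CaOV-3 and RMG-I the G1/S and E2F target genes rose while the G2/M genes fell. The choice among 4 library scalings is argued against, since the lowest median G1/S change over them and both lines was 0.309. All 4 left the median change of all genes between −0.0089 and 0.025, so they could not show a change in total RNA per cell. Little RB1 transcript is argued against in RMG-I, which had the most RB1 in DMSO (90.7 CPM), and cannot be told apart in CaOV-3 (1.09 CPM), since the next lowest line had 12.7 CPM. The dose is argued against in CaOV-3 by FU-OV-1, treated at the same dose, where the median was −0.947. For RMG-I the dose stays open, since no other line had its dose, the highest median at the adjacent doses was 0.0631 and the G1/S change rose with log2 dose over the lines (r = 0.605).

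Other splits of the samples were counted for each model over genes. Across lines 1 of 60 splits, the real one with 2064 genes, gave as many, and the highest other gave 0, so relabelling did not reach this count. Between lines 1 of 40 splits, the real one with 4987 genes, gave as many, and the highest other gave 1546. Those splits relabelled the libraries within each line, which leaves part of the treatment effect in a line, with a sign that varies from line to line. They therefore cannot tell a difference between lines from an effect that all lines share. Against dose the real count was 0, which every split reaches (60 of 60 in DMSO, highest other 82, and 40 of 40 for the change, highest other 0), so these splits say nothing about chance. Within a line the 10 splits are too few for a share under 0.05, and the real count and the highest other were 740 and 3 in A2780, 3512 and 1 in CaOV-3, 948 and 1 in COV318, 1902 and 2 in COV434, 271 and 2 in COV644, 4425 and 2 in FU-OV-1, 2506 and 0 in Kuramochi, 0 and 12 in OAW42, 106 and 1 in NIH:OVCAR-3, 449 and 3 in OVMANA, 1392 and 0 in OVSAHO, 3677 and 1 in RMG-I, 323 and 0 in RMUG-S, 442 and 1 in SK-OV-3, 1879 and 1 in TOV-112D and 14 and 1 in TOV21-G. In OVISE the real split gave 21 rises and 87 falls and the highest other 0 genes. The count as large was 1 of 10 splits in each of these lines except OAW42, with 10 of 10. In OV-90 (10 of 10) the real split gave 0 genes by edgeR and another split 4584, which points to a structure of the samples. In this line the ribosomal RNA share was 4.39%, 3.72% and 8.41% in DMSO and 3.26%, 7.37% and 6.78% in BLU-222.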

How the results depend on the processing

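The GC trend, the ribosomal RNA settings, the removal of libraries that stood apart and the removal of genes low against the other lines were chosen after seeing the data. Of 4477 values under alternatives, 3903 kept their direction and side of the threshold (counts within 1.5 times), 444 no longer passed, 11 passed in addition, 105 moved further and 14 changed sign. For the 20 genes with the largest changes across lines, 12 of 600 values no longer passed, all of PLAU or MYO15B. For the 100 genes named across lines 200 of 2984 no longer passed, and for the 32 named within a line 29 of 352. Except where a cause is given, the cause was not tested.

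Across lines the count of 2064 genes ran from 1361 to 1621 without a replicate, with fewer libraries, and from 1508 without FU-OV-1 to 2172 without TOV21-G. CDKN1A, at −0.01 on the log2 scale, turned to 0.00809 with the ribosomal RNA covariate, 0.0158 without Kuramochi, 0.019 without OVMANA and 0.000932 without RMUG-S, and ran from −0.0473 to 0.00602 without a replicate. With an estimated correlation 0 lists passed across lines (G1/S adjusted p = 0.339, G2/M 0.0698), 3 within lines and 0 against dose. By fry the G1/S (adjusted p = 0.0492) and G2/M (1.6e-05) lists passed across lines. The stress response list turned its direction with adjusted p = 0.968 in the replicate block and 0.628 with the covariate. This list also turned without replicate 1 (0.93) and without replicate 3 (0.853), and held its direction without replicate 2. Its adjusted p without a replicate ran from 0.557 to 0.93. The direction also turned for apoptosis regulators without replicate 3 (0.869), fibroblast markers without replicate 1 (0.919) and leukocyte markers without replicate 2 (0.978). For each of these lists it held without either of the other replicates. Without a replicate the adjusted p ran from 0.455 to 0.919 for apoptosis regulators. It ran from 0.36 to 0.919 for fibroblast markers and from 0.787 to 0.978 for leukocyte markers. Without genes low against the other lines the direction turned in TOV-112D for the epithelial arm (camera adjusted p = 0.981) and the lineage genes (0.417). The epithelial arm keeps few members there, since 31 of its 34 genes stood under 5% of the other lines' level.

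The replicate numbers did not pair the samples: the correlation of same-numbered deviations ran from −0.186 to 0.159 (median 0.002), and 0 lines had every pair over 0.1. With the replicate block the count was 4352 across lines, 678 for the change against dose, 1457 in COV318, 17 in OAW42, 165 in OVMANA and 2428 in OVSAHO. Across lines and against dose this block takes the replicate pairs of a line as independent units in place of the line. Those counts therefore do not rest on lines as replicates.

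Within lines, 1 fit of all libraries with a shared spread called 23 genes in A2780, 585 in CaOV-3, 2324 in COV318, 376 in COV434, 1243 in COV644, 2506 in FU-OV-1, 546 in Kuramochi, 29 in OAW42, 74 in OV-90, 1388 in NIH:OVCAR-3, 1407 in OVISE, 1451 in RMG-I, 132 in SK-OV-3 and 480 in TOV-112D. No filter on low counts gave 1500 in COV318, 907 in COV644, 7 in OAW42, 721 in OVMANA, 799 in SK-OV-3 and 246 in TOV21-G. The ribosomal RNA covariate gave 210 in COV318, 11 in COV644, 952 in Kuramochi, 755 in OV-90, 0 in NIH:OVCAR-3, 2562 in OVISE, 2122 in OVSAHO, 71 in RMUG-S and 41 in SK-OV-3. DESeq2 gave 569 in COV644, 10 in OAW42, 59 in OV-90, 255 in NIH:OVCAR-3, 343 in OVISE and 495 in RMUG-S.

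Single libraries moved the count of their line by over 1.5 times. In A2780 it was 319 without DMSO 2, 455 without DMSO 3 and 272 without BLU-222 1 (range 272 to 1050). In COV318 it was 447, 2069 and 424 without DMSO 1, 2 and 3, and 604, 535 and 432 without BLU-222 1, 2 and 3. In COV434 it was 1224 without BLU-222 2 and 1139 without BLU-222 3 (range 1139 to 1760). In COV644 it was 15, 34 and 131 without DMSO 1, 2 and 3, 62 without BLU-222 2 and 680 without BLU-222 3. In OAW42 it was 7 without DMSO 1, 1 without BLU-222 2 and 9 without BLU-222 3 (range 0 to 9). In NIH:OVCAR-3 it was 22, 21 and 27 without DMSO 1, 2 and 3, 25 without BLU-222 1 and 217 without BLU-222 2. In OVISE it was 879 without DMSO 1, 57 without DMSO 2, and 0, 4 and 0 without BLU-222 1, 2 and 3. In OVMANA it was 252 without DMSO 3 and 256 without BLU-222 2 (range 252 to 432). In OVSAHO it was 2129, 705 and 711 without DMSO 1, 2 and 3 and 736 without BLU-222 3. In RMUG-S it was 131 without DMSO 1 and 122 without BLU-222 3 (range 122 to 470). In SK-OV-3 it was 700, 168 and 736 without DMSO 1, 2 and 3, and 187, 111 and 118 without BLU-222 1, 2 and 3. In TOV-112D it was 1174 without BLU-222 3 (range 1174 to 1549). In TOV21-G it was 36, 5 and 152 without DMSO 1, 2 and 3, 41 without BLU-222 1 and 1 without BLU-222 2.

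Expression in DMSO against dose, with 0 genes by edgeR, gave 276 with no filter, 80 with dose in nM, 1 without the lines at the lowest and highest dose, 26 without the libraries that stood apart, 897 by DESeq2 and 0 to 26 without a replicate, of which 26 without replicate 1. The change against dose gave 21 by DESeq2. The count of genes that differed between lines ran from 1773 to 2591 without a replicate, with fewer libraries. With dose in nM, 0 of the list relations passed by r (0.486 for the G1/S and 0.44 for the G2/M genes), and without replicate 2 the G2/M genes did not pass by rho (0.498, adjusted p = 0.0551). In simulated data with a dispersion of 0.5 between lines, slopes of 0.5 in DMSO were recovered for 30% of genes, and what depth limits was not separated from this spread.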

Other observations

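The relations between regulators and list changes, and the test of CCNE1 at a fixed dose, were chosen after the results were seen. CDK2 transcript in DMSO was highest in TOV-112D, at 176 ± 5.68 CPM (SD, n = 3), and CaOV-3, at 173 ± 3.59, and lowest in COV318, at 49.1 ± 3. CDKN1A was highest in TOV21-G, at 588 ± 32 CPM in DMSO and 538 ± 27.8 in BLU-222. CDKN1B was called lower in 8 lines and higher in 0 by edgeR, with log2 changes from −0.52 in RMUG-S to −0.08 in TOV21-G. CDK1 was called lower in 9 lines, from −1.76 in OVSAHO, and CCNE2 higher in 5 lines and lower in 4, from −2.17 in COV318 to 0.97 in COV644. In FU-OV-1, the line with the most CCNE1 transcript, CCNE1 went from 230 ± 10.5 to 133 ± 9.4 CPM, and in RMG-I from 25 ± 1.92 to 51.5 ± 2.78 CPM.

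Over the 18 lines, 11 relations were computed between regulators in DMSO, ribosomal RNA share and list changes. The median change of the G1/S genes went with that of the G2/M genes (r = 0.797, permutation p = 6e-05, adjusted 0.00066; rho = 0.802, permutation p = 0.0001), with r = 0.758 without the 2 lines farthest from the median of the x axis. CCNE1 in DMSO had r = −0.749 with the G2/M change (permutation p = 0.00029, adjusted 0.00159; rho = −0.742, permutation p = 0.00055) and r = −0.66 without 2 lines. With the G1/S change CCNE1 had r = −0.687 (permutation p = 0.00159, adjusted 0.00583; rho = −0.74, permutation p = 0.00061) and r = −0.561 without 2 lines. CDKN2A had r = −0.54 with the G1/S change (permutation p = 0.0212, rho = −0.624, r = −0.436 without 2 lines) and −0.542 with the G2/M change (permutation p = 0.0213, rho = −0.651, r = −0.474 without 2 lines), with adjusted 0.0468 for both r. RB1 had r = 0.254 with the G2/M change (permutation p = 0.326, adjusted 0.58; rho = 0.447, permutation p = 0.0649) and r = 0.546 without CaOV-3 and OVSAHO. With the G1/S change RB1 had r = −0.0844 (permutation p = 0.743, adjusted 0.817; rho = 0.284, permutation p = 0.253) and r = 0.43 without the same lines, so these values rest on them. The difference in ribosomal RNA share had r = −0.0863 with the G2/M change (permutation p = 0.73, adjusted 0.817).

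A hypothesis from these values is that lines with more CCNE1 transcript before treatment may lose more G2/M transcripts with BLU-222 at their IC50. At a fixed log2 dose the partial correlation of CCNE1 with the median G2/M change was −0.633 (permutation p = 0.00427, n = 18 lines, −0.56 without 2 lines), while that of dose at a fixed CCNE1 level was 0.186. The relation was found and tested on the same 18 lines, dose is tied to the sensitivity of each line, and other differences between the lines were not tested.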
